A study of Drosophila melanogaster with 4 samples.

How the data were processed

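Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos collected between 12 and 24 h of age. Per the labels, the embryos carried a transgene of the genomic coding region of the lola transcript RJ, named PJ for the protein in the series title, tagged with green fluorescent protein (GFP). The extraction protocol in the labels names flies of another genotype (marked with y, bw, cn and sp), and the labels do not resolve this difference. The series holds 4 libraries: 2 from chromatin precipitated with a polyclonal rabbit antibody against GFP, and 2 of input DNA, genomic DNA of the kind commonly used as background for enrichment. Titles number the libraries 1 and 2 in each group. The labels do not say whether the numbers stand for separate embryo collections.

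One peak list was analysed. Per the submitters' processing notes, the tools included CASAVA (versions 1.7.0.2 and 1.7.0.3), BWA and MACS2, and the genome build was BDGP5. Per the file headers, coordinates are those of FlyBase release 5, and the source column names MACS. The versions of BWA and MACS2, their settings and cut-offs, and whether the replicate libraries were pooled before peak calling are not given in the sources used here. Each peak has a start, an end and 1 score. The score is the authors' deposited value, with 2 decimals, and its formula (a p-value, a q-value or a fold enrichment) is not named in the file. It was therefore used only within the list, to describe, rank and filter peaks, to compare sets of peaks and to relate it to peak width. The list carries 1 score per peak and names no library. No value could be split by library, so no replicate error exists for any peak and no SD over replicates is given. The SDs printed are over windows of the genome. Sequencing depth per library is not given in the sources used here. Read counts per peak were not used here, so the precision of single scores is unknown. All intervals below cover counting error over peaks only, at the 95% level.

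The peak numbers in the list ran from 1 to 2922 with 0 missing. This excludes gaps within the run, but not peaks cut from its end or a list numbered anew. No peaks overlapped. The narrowest peaks measured 201 bp, the width of 48 peaks, and the smallest gap between neighbours was 50 bp. Gaps of at most 200 bp made up 7.05% of all gaps (205 gaps), so nearby peaks can be parts of one enriched region, and counts of peaks depend on how such parts are joined.

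The genome and annotation of release 5 were not used here. The gene table that was used belongs to release 6, and coordinates were neither mixed nor converted between the releases. Of the results planned before the data were examined, 5 were not computed for this reason: the share of peaks at promoters, the annotation classes of peaks, the tests of 21 gene lists, the shares of 24 motifs, and the peaks at the lola gene. The rule for naming genes (the gene with the nearest transcription start site to each of the 25 peaks with the highest score, list members with a peak at a start site, and genes at the lola locus) could not name any gene, so regions are named by coordinates. The planned test of peaks per arm against arm length was changed after the data were seen: the span from the first peak start to the last peak end stood in for arm length.

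Analyses were run in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. The main arms are 2L, 2R, 3L, 3R, 4 and X. Peaks per arm were tested against the arm's share of the summed spans by a two-sided exact binomial test with Benjamini-Hochberg adjustment over the 6 arms. Densities have exact Poisson intervals. This test treats peaks as independent, which closely spaced peaks are not, and so gives p-values that are too small. A permutation test over 100-kb windows was run beside it, which still takes neighbouring windows as independent. Spacing was the median distance between neighbouring peak centres on an arm, tested against 1000 uniform placements of the same number of centres within the span (two-sided permutation test, smallest possible p = 0.002). Peaks up to 10 kb apart were also joined into groups. Scores of sets of peaks were compared by permutation of the difference of medians (10000 resamples) and by Fisher's exact test of the share of peaks with a score of at least 100, each adjusted over 5 comparisons. These comparisons and the score of 100 were not among the planned results, and both tests treat grouped peaks as independent. Shares have Wilson intervals. The relation of score to width was tested with 100000 permutations and adjusted over 13 relations. Peaks are not replicates, so these p-values describe this list and not the spread between embryos.

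In simulated peak lists the count of each arm was drawn at random around its share of 2515 peaks. With peaks placed independently and uniformly and no difference between arms, the arm test called 1.17% of arm tests. The listed peaks are closely spaced, so this is not the rate of false calls for the list itself. With a 5-fold density planted on chromosome 4 it called that arm higher in 100% of 100 lists, with a mean recovered ratio of 4.92. The spacing test, on 20 lists of each kind, passed its threshold on 5% of arm tests of uniform peaks. It passed on 100% of the arms other than 4 where all peaks were planted in groups of 4. All planted groups of an arm had the same spacing. Of the listed main-arm peaks 38.3% stood alone, so this check covers only grouping stronger than that of the list.

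The alternatives were the 1462 peaks with a score of at least 19.35 (the list's median), covered bases in place of peak counts, and leaving out arm X from the score relation. Those added after the data were seen were spans from position 1, joining peaks up to 1 kb or 10 kb apart, leaving out the largest block of peaks or chromosome 4, windows in place of peaks, placements without overlap, and the score relation in the 1193 main-arm peaks with a score of at least 19.35 and outside the main arms.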

Results

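The data were a list of 2922 peaks called for GFP-tagged Lola in embryos aged 12 to 24 h, from a series of 2 GFP ChIP and 2 input libraries. Which of these libraries entered the peak call is not given in the sources used here. Lola (longitudinals lacking) is a family of BTB-domain transcription factors, most of them with zinc fingers, made by alternative splicing from one gene and known for roles in axon growth and guidance. The labels name the transcript RJ and the protein PJ. The antibody was directed against the GFP tag, so the list asks where the tagged isoform sat on the genome. The series holds no GFP precipitation from embryos without the tag, so DNA recovered without the tagged isoform cannot be told apart. The list holds neither a value per library nor a comparison between conditions. The comparisons that follow are therefore between regions of the genome, and no replicate error can be attached to a peak.

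The peaks covered 1740 kb in all. Their median width was 452 bp (middle 50% of peaks, 297 to 731 bp; widest, 4503 bp). The median of the authors' score was 19.4 (middle 50% of peaks, 12.1 to 36.9; range, 5.86 to 366.91), and 200 peaks, or 6.84%, had a score of at least 100. The 6 main arms held 2515 peaks, or 86.1%. The other 407 peaks lay on 7 sequences outside them.

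The strongest peaks were spread over the genome. The highest score, 366.91, belonged to a peak on arm 3L at 6117924 to 6119228 (release 5). It was followed by a peak on X at 14476655 to 14478184 with a score of 347.12, and one on 3R at 8889374 to 8890736 with a score of 332.06. The next were a peak on 2R at 15993654 to 15994480 with a score of 327.19 and another on 3R at 8537554 to 8538876 with a score of 312.27. Of the 25 peaks with the highest score, 7 lay on 3R, 5 on 2L, 5 on X, 3 on chromosome 4, 2 on 3L, 1 on 2R, 1 on 2RHet and 1 on 3LHet. Stronger peaks were wider. Across the 2515 main-arm peaks, width and score had a Spearman rho of 0.79 (permutation p = 1e-05, the smallest the resamples can give; adjusted p = 1e-05) and a Pearson r of 0.62 (permutation p = 1e-05, adjusted p = 1e-05). Pearson r was 0.62 without the 2 peaks whose width lay farthest from the median. Within single arms rho ran from 0.74 on 3L to 0.83 on chromosome 4. Width and score come from the same peak call, so the calling itself may tie them together. The permutation test cannot tell this apart from a property of the bound sites.

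**Figure D1:**
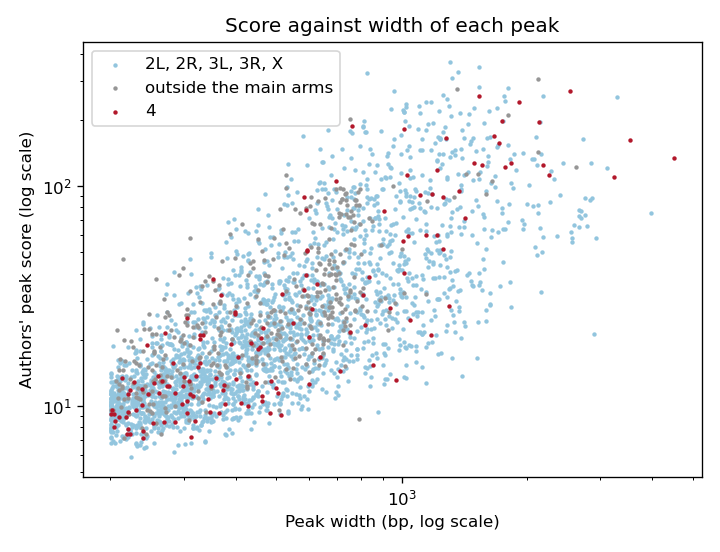
Authors' peak score against peak width in bp, both on log scales, with 1 point per peak for all 2922 peaks, coloured by chromosome 4, the 5 larger arms and the sequences outside the main arms. Score rises with width in each set (Spearman rho 0.79 over the main arms).

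The question of where along the genome the peaks lay was asked first by chromosome arm. Chromosome 4, the small and largely heterochromatic dot chromosome, carried 140 peaks over a span of 1.28 Mb, or 109 peaks per Mb (95% Poisson interval, 91.7 to 129). The 5 larger arms together carried 20.0 peaks per Mb, so the density on chromosome 4 was 5.45 times theirs (exact binomial test, adjusted p = 1.31e-53). Densities on the larger arms lay close together: 22.5 per Mb on 2R (20.5 to 24.6), 20.9 on X (19.0 to 22.8), 20.7 on 2L (18.9 to 22.7), 18.4 on 3L (16.8 to 20.2) and 18.2 on 3R (16.6 to 19.8). The excess on chromosome 4 was also present in covered sequence, with 77.7 kb of peaks per Mb against 12.0 kb per Mb on the larger arms. When peaks up to 10 kb apart were joined, the excess fell from 5.45 to 2.77 times and stayed past the threshold (exact binomial test, adjusted p = 5.68e-08).

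The X chromosome did not stand apart from the other arms, with 0.995 times the density of the rest (exact binomial test, adjusted p = 0.939). On 3L and 3R the density was 0.85 and 0.83 times that of the other arms (exact binomial test, adjusted p = 0.0039 and 0.00075). These 2 calls were lost over 100-kb windows, at similar ratios of 0.85 and 0.84 (permutation p = 0.10 for 3L and 0.061 for 3R), and when peaks up to 1 kb apart were joined, at 0.94 and 0.88 (adjusted p = 0.34 and 0.072). Without chromosome 4 among the other arms, the call on 3L was lost at 0.90 (exact binomial test, adjusted p = 0.084). The call on 3R was kept at 0.88 (exact binomial test, adjusted p = 0.036). Arms 2L and 2R did not pass the exact binomial test (adjusted p = 0.94 and 0.14). The result for 2R, 1.09 times the other arms, depended on the setting: it passed the exact test at 1.17 among peaks with a score of at least 19.35 (adjusted p = 0.045), at 1.13 without the largest block of peaks on 2L (adjusted p = 0.023) and at 1.16 without chromosome 4 (adjusted p = 0.026).

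**Figure D2:**
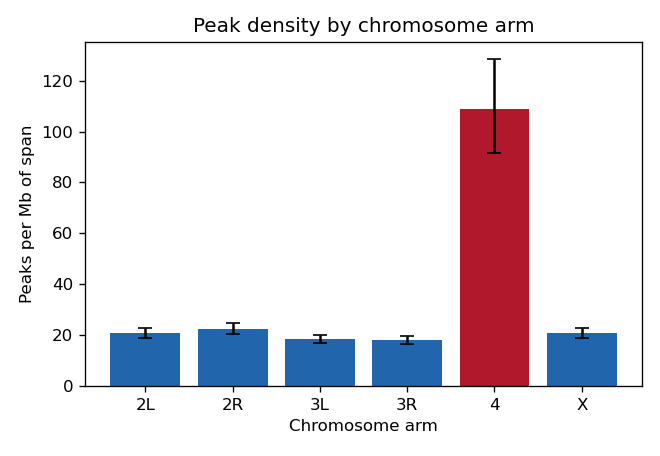
Peaks per Mb of the span between the first and the last peak, by chromosome arm, with bars for the density and error bars for the exact 95% Poisson interval, which covers counting error over peaks only. Chromosome 4 stands at 109 per Mb and each of the other arms between 18.2 and 22.5 per Mb.

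Peaks on chromosome 4 were found all along its span, which runs from 62997 to 1347730. The first and the last window of 100 kb therefore lie only partly within it. All 14 windows of 100 kb held at least 3 peaks, with a mean of 10.0 ± 3.53 (SD over windows). On the 5 larger arms the mean was 1.99 ± 2.58 over 1192 windows, and 30.1% of windows held no peak. The difference of means was larger than chance over windows (permutation p = 1e-05, the smallest the resamples can give). Each window of chromosome 4 exceeded the mean of the larger arms, and 12 of the 14 exceeded their 95th percentile of 6 peaks. Only 14 of the 1192 other windows held at least as many peaks as the mean window of chromosome 4.

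**Figure D3:**
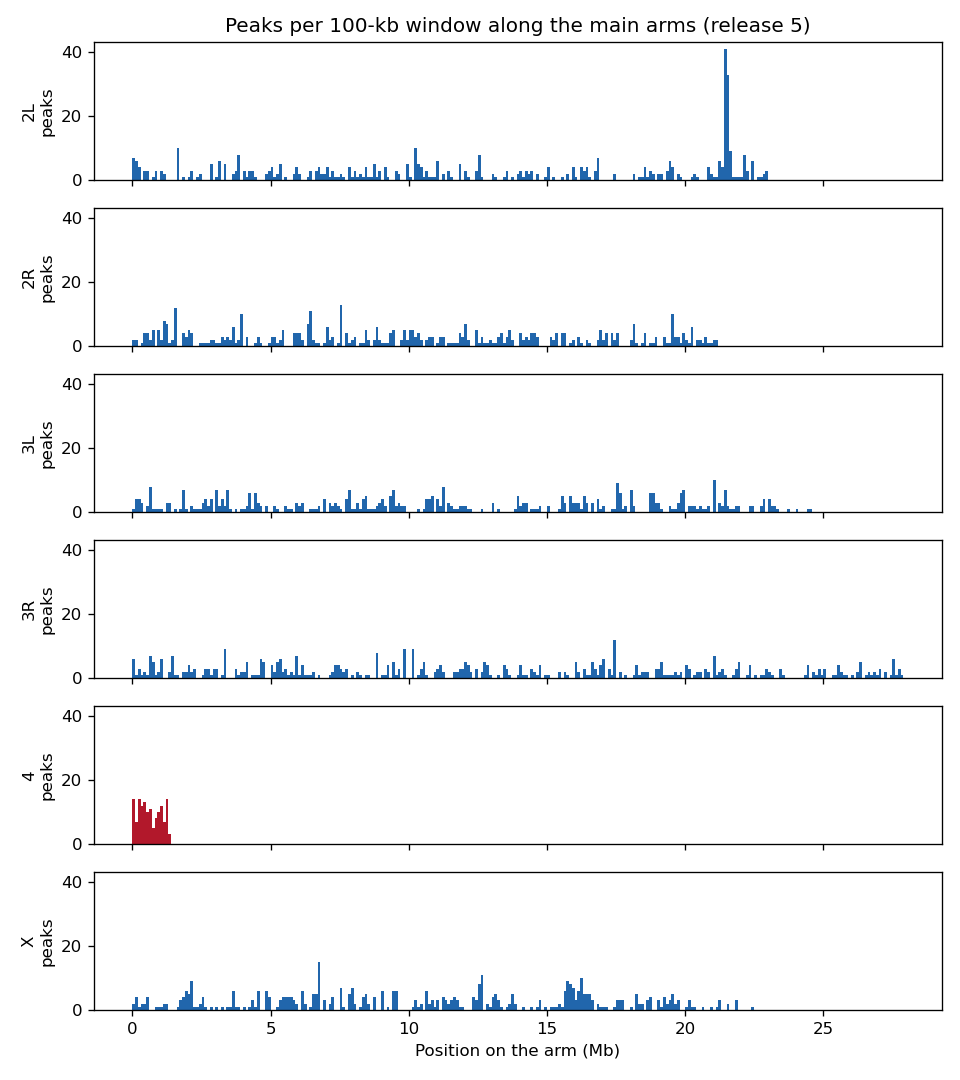
Number of peaks in each 100-kb window (y axis) along the 6 main arms (x axis, position in Mb, release 5), with 1 panel per arm on common axes and chromosome 4 in red. Each window of chromosome 4 holds at least 3 peaks (mean 10.0 per window), and 2L has a single tall block of peaks near its right end.

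Strong peaks were also more frequent on chromosome 4. There, 22 of 140 peaks (15.7%; 95% Wilson interval, 10.6 to 22.6%) had a score of at least 100, against 167 of 2375 (7.03%; 6.07 to 8.13%) on the larger arms (Fisher's exact test, adjusted p = 0.0018). Neither the comparison nor the score of 100 was planned. Grouped peaks count as independent in this test, so its p-value can be too small. Median scores, 16.7 against 18.4, did not differ past the threshold (permutation test, adjusted p = 0.38). On X, 7.71% of peaks had such a score, against 6.87% on the 4 other larger arms (Fisher's exact test, adjusted p = 0.54). The widest peak in the list, 4503 bp, lay on chromosome 4 at 680021 to 684523 and had a score of 134.18.

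Peaks on the larger arms came in groups. The median distance between neighbouring centres was 13.7 kb on 2L, 14.6 kb on X, 18.8 kb on 2R, 22.0 kb on 3L and 22.8 kb on 3R, between 0.41 and 0.61 times the distance under uniform placement (permutation test, adjusted p = 0.002 on each arm, the smallest the placements can give). On chromosome 4 the median distance was 3.51 kb, 0.55 times that of uniform placement (permutation test, adjusted p = 0.002). The call on chromosome 4 was lost in 2 alternatives. With peaks up to 1 kb apart joined, the ratio there was 1.09 (permutation test, adjusted p = 0.38), whereas on the larger arms it was 0.58 to 0.77 (adjusted p = 0.0024 on each). Among peaks with a score of at least 19.35, none of them joined, it was 0.76 (permutation test, adjusted p = 0.062). With peaks up to 10 kb apart taken as 1 group, the main arms held 1476 groups, and 964 peaks stood alone. Groups of 5 or more took 53.6% of the peaks of chromosome 4 and 13.2% of those of the larger arms. On chromosome 4, 67.6% of the distances between neighbouring centres were at most 10 kb, against 66.4% under uniform placement. On the larger arms the observed shares ran from 33.6% on 3R to 44.8% on 2L, and those under uniform placement from 16.6% to 20.2%.

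Only 5 groups held 10 or more peaks. By far the largest lay on 2L at 21416554 to 21543532, with 68 peaks in 127 kb. Its peaks covered 64.7% of the block and made up 14.3% of all peaks on 2L and 25.5% of the covered sequence there. In 1000 uniform placements the largest group on the larger arms held 9 peaks at most. The block's median score, 26.2, was higher than that of the rest of 2L, 17.0 (permutation test, adjusted p = 0.0055), yet none of its 68 peaks reached a score of 100 (0%; 95% Wilson interval, 0 to 5.35%). Elsewhere on 2L, 35 of 408 peaks did (Fisher's exact test, adjusted p = 0.0065). Both score tests treat the 68 peaks as independent. Their p-values would be too small if the block holds repeated units, a possibility taken up below. The 22 peaks of the block with a score of at least 50, a minimum chosen after the values were seen, had a median distance of 5066 bp between neighbouring centres. Without this block and its sequence the density on 2L was 17.9 peaks per Mb. With only the block's peaks left out, 2L had 0.85 times the density of the other arms (exact binomial test, adjusted p = 0.0061). The block's sequence and the groups of the other arms were kept in this test, so the ratio of 2L was lowered by construction. With the block kept and peaks joined on every arm, 2L did not pass the exact test, at 0.89 with joining up to 1 kb (adjusted p = 0.091) and 0.91 with joining up to 10 kb (adjusted p = 0.37).

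**Figure D4:**
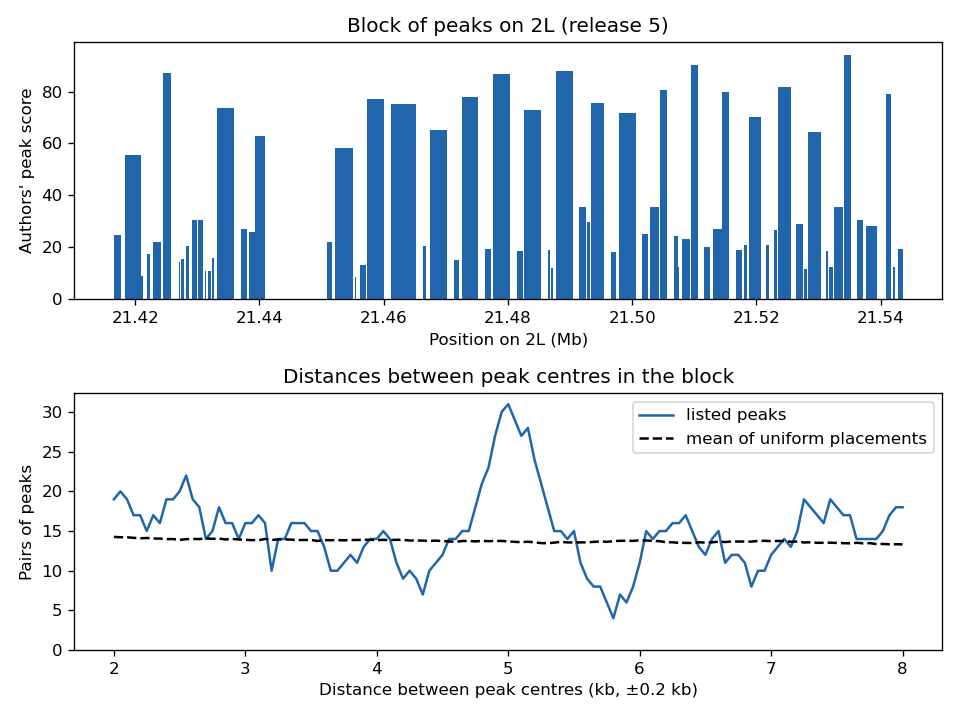
Upper panel, position in Mb (x axis, release 5) and authors' score (y axis) of each of the 68 peaks in the block on 2L. Lower panel, number of pairs of peak centres at each distance in kb, for the listed peaks (line) and the mean of 1000 uniform placements (dashed); the line has its maximum of 31 pairs at 5000 bp.

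The other groups of 10 or more were smaller. On X, 14 peaks lay at 6746060 to 6769308, among them the peak with the eighth highest score of the list, 279.58. On chromosome 4, 14 peaks lay at 62997 to 91093 and 10 at 455188 to 489810. On 2L a second group of 10 peaks lay at 1627407 to 1657251, with a highest score of 84.44.

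Peaks of lower and of higher score were found near peaks with a score of at least 100. On the larger arms, 22 of the 167 peaks with a score of at least 100 (13.2%) lay within 10 kb of another such peak, edge to edge, as did 115 of the 2208 weaker peaks (5.21%). On chromosome 4 the corresponding shares were 8 of 22 (36.4%) and 51 of 118 (43.2%). The difference between these shares was not tested, and no rotation was run for stronger peaks near each other. Measured between centres, 4.85% of the weaker peaks on the larger arms lay within 10 kb of a stronger one, against 2.70% when the stronger peaks were rotated along their arms (one-sided permutation test over 1000 rotations, adjusted p = 0.004). On chromosome 4 the shares were 41.5% of 118 peaks and 29.1% after rotation (the same permutation test, adjusted p = 0.023). The rotations used peaks as listed and were not run on joined peaks. Weaker peaks that the caller split off a stronger one are therefore not told apart from separate sites.

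At the centromere ends of their spans the arms differed in direction. In the 2 Mb at the centromere end of the span, X carried 6.0 peaks per Mb against 22.3 on its remainder, 0.27 times as many (95% interval, 0.14 to 0.47; exact binomial test, adjusted p = 9.38e-08). On 3L the corresponding densities were 9.5 and 19.2 per Mb, a ratio of 0.49 (0.29 to 0.78; exact binomial test, adjusted p = 0.0023). On 2R they were 32.0 and 21.5 per Mb, a ratio of 1.49 (1.13 to 1.94; exact binomial test, adjusted p = 0.0058), and on 3R 25 and 17.7 per Mb, a ratio of 1.42 (1.04 to 1.90; adjusted p = 0.025). On 2L the ratio was 3.69 with the block of 68 peaks and 1.67 (1.23 to 2.21; exact binomial test, adjusted p = 0.0020) without its peaks. The block's sequence was kept in that ratio. The size of the region was chosen after the data were seen, and these tests treat grouped peaks as independent. Peaks on the Het sequences (assembled heterochromatin of the arms) did not enter them. Mappability and gaps in the assembly at these ends were not tested.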

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

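The tests of chromosome 4 below were chosen after the densities had been seen, and those of the block on 2L, except the choice of the block itself, before their results were.

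Peaks outside the main arms were flagged as signal in sequence that the comparisons between arms do not use. There were 407: 332 on Uextra (small unplaced scaffolds), 27 on U (unplaced scaffolds), 21 on 2RHet, 16 on 3LHet and 8 on 3RHet (assembled heterochromatin of those arms), and fewer than 4 on each of the others. The 48 peaks on the Het sequences had a median score of 43.5 against 18.4 on the main arms (permutation test, adjusted p = 0.00025), and 20.8% of them (95% Wilson interval, 11.7 to 34.3%) had a score of at least 100 against 7.51% (Fisher's exact test, adjusted p = 0.0051). Peaks on U and Uextra together had a median score of 23.9 (permutation test, adjusted p = 0.00025), with 24.7 on Uextra and 17.5 on U, the latter below the main arms. Of these peaks, only 1 of 359 reached 100 (0.279%; Wilson interval, 0.0492 to 1.56%; Fisher's exact test, adjusted p = 9.54e-10). No explanation of these values was tested.

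The density of peaks on chromosome 4 could come from broad enrichment that the caller split into many peaks. After joining peaks up to 10 kb apart, chromosome 4 still had 2.47 times the density of 2R, the densest other arm (95% interval, 1.75 to 3.42). Before joining it had 4.85 times that density. This argues against splitting into pieces up to 10 kb apart as the whole cause. Pieces farther apart stay unjoined, so the joining cannot decide on broader enrichment split at that scale. Joining lowers the ratio of a denser arm even without splitting, so the fall does not show that splitting had a part, and a partial role stays open. A surplus of weak peaks near the calling threshold is argued against by a ratio of 7.86 (4.51 to 13.3) among peaks with a score of at least 100, and a single dense stretch by the 85.7% of 100-kb windows above the 95th percentile of the other arms. Copy number, mappability and the background in input DNA on this chromosome, and gene density, were not tested. Recovery of DNA without the tagged isoform and any biological explanation were not tested either. The list holds no signal per library, and the design has no other factor, stage or genotype.

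The block of 68 peaks on 2L may lie on a tandem repeat array with a unit of about 5 kb. Distances between its peak centres were in excess at a lag of 5000 bp, with 31 pairs within 200 bp of it against 13.7 under uniform placement (permutation test over lags from 2 to 8 kb, p = 0.002). The placed centres could overlap, while the listed peaks do not and cover 64.7% of the block. Placements without overlap were not run for this scan, so how far peak widths add to the excess is unknown. The same scan on chromosome 4 gave a best lag of 2500 bp (permutation p = 0.052). The histone gene cluster is a candidate identity: a run of 111 neighbouring histone genes lies on 2L in the release 6 gene list and on no other arm, but the list's positions belong to another build, which keeps this open. Reads shared between near-identical units would make the height of single peaks there uncertain, and whether enrichment over input or unit number set the scores was not tested.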

How the results depend on the processing

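The deposited list gives 1 set of peaks, so the results depend mainly on which peaks are counted and how neighbours are joined. No paired analysis was possible because the list has no value per library, and for the same reason no replicate could be left out. Promoter-based alternatives (a second window, gene-list and motif settings, promoter peaks only) were not run, since release 5 annotation was not used here. Of 78 alternatives, 64 changed no called direction, no side of the threshold and no untested value by over 1.5 times. That count includes spacing with the block on 2L left out on the arms that hold none of its peaks, where the peaks stayed the same. The excess on chromosome 4 stayed past the threshold in each tested setting, from 2.77 times (10-kb joining) to 5.61 times (block left out), and was 6.48 times in covered bases. Keeping scores of at least 19.35 left 1462 peaks, put 2R past the threshold at 1.17 times the other arms, and left the spacing ratio on chromosome 4 at 0.76, no longer past it. Joining peaks up to 1 kb apart reversed the spacing ratio on chromosome 4 to 1.09 (range over its alternatives, 0.54 to 1.09) and took 3L (0.94) and 3R (0.88) out of the calls. Joining up to 10 kb gave 0.93 and 0.96 there, and windows of 100 kb gave 0.85 and 0.84, none past the threshold. Leaving out the block on 2L put 2L (0.85) and 2R (1.13) past it, and leaving out chromosome 4 put 2R (1.16) past it and took 3L (0.90) out. Fewer, larger units explain part of the losses under joining and windows by construction. Leaving out the block lowers the ratio of 2L by construction, and the cause of the other changes was not tested. Spacing on the 5 larger arms and the relation of score to width (rho 0.58 to 0.78) kept direction and side in each alternative. Depth per library is unknown, so what it limits cannot be stated.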

Other observations

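Each observation here was made after the data were seen.

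Single stretches of the larger arms also carried many peaks. The megabase from 16 to 17 Mb on X held 40 peaks and the one before it, from 15 to 16 Mb, held 36. From 6 to 7 Mb on X there were 37 peaks, and from 1 to 2 Mb on 2R there were 39. In 1000 uniform placements the fullest megabase of the larger arms had a median of 33 peaks and at most 46, so these 4 counts lie between the median and the highest of the placements, and no p-value was computed for them. The megabase from 21 to 22 Mb on 2L, with 98 peaks, lies above the highest placement and contains the block of 68 peaks.

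The stronger peaks on Uextra were narrower than main-arm peaks in the same range of scores. Scores were not matched within that range, and width rises with score. Over all peaks the median width was 506 bp on Uextra and 446 bp on the main arms. The 40 Uextra peaks with a score of at least 60 had a median width of 723 bp (middle 50% of peaks, 608 to 759 bp). The 236 main-arm peaks with a score from 60 to 111.89 had a median width of 969 bp (739 to 1373 bp; permutation test of the medians of log2 width, p = 0.0025). The lengths of the scaffolds in Uextra were not used here, and a limit on peak width by scaffold ends was not tested.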
